A study of Mus musculus with 15 samples.

How the data were processed

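Total RNA from mouse ventral prostate epithelial cells was measured on 15 biotin-labelled arrays, 3 in each of 5 groups: untransduced primary cultures (control) and lines transformed with Myc, NeuT, Ras or Src. Per the labels, RNA was extracted with Trizol and amplified with the WT-Ovation Pico system, and cells were harvested at 85-90% confluence. The deposited values are on the log2 scale and were normalized across arrays by the authors. RMA and Affymetrix Expression Console 1.1 are named in the submitters' processing notes, with no role or order given. Background settings, the summary level and the genome build are not given in the sources used here, so no coordinates are printed.

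The table held 35556 probe sets, of which 21789 were assigned to 1 gene, 1621 to several and 12146 to none. Probe sets with 1 gene were used, and for the 999 genes with several of these the one with the highest mean over the 15 arrays was taken, which gave 19938 genes. Entrez identifiers matched 21698 of the single-gene probe sets to the reference annotation, and 0 symbols were changed. Probe sets with several genes or none were not used in the comparisons and were counted separately. Genes without a probe set of their own, among them Hras, were not analysed here. No filter on low values was applied.

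A linear model with 5 group means was fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that all groups shared 1 estimate of the spread. Contrasts were the mean of the 4 oncogene groups against control, each oncogene against control, each oncogene against the mean of the other 3, and the 6 pairs of oncogenes. An F test covered differences among the 4 oncogene groups. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested. Genes were called at an adjusted p under 0.05 and a fold change of at least 2, or for the F test a range of at least 1 (log2) between group means. Members of a list rose or fell at an adjusted p under 0.05 with no fold minimum. Errors of fold changes are SE from limma and those of group levels are SD. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

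Markers and pathways were covered by 26 gene lists, of which 25 had at least 4 measured members and were tested with camera in limma at a preset correlation of 0.01. Adjustment was over the 25 lists, and lists were called at an adjusted p under 0.05. The same test was run with a correlation estimated from each list's residuals, and fry tested whether each list's genes moved on balance 1 way. The Y-linked list, with 3 measured genes, was given gene by gene. Named genes were, for each contrast with control or with the other oncogenes, the 6 highest and 6 lowest fold changes among genes with an adjusted p under 0.05, a higher group mean at or above 6.47 (the median of all gene values) and no overlap between the arrays of the sides. Predicted genes were passed over. The transduced genes, up to 4 members of each called list and up to 2 of each other list, by smallest p, were added. The groups, contrasts, thresholds, lists and this rule were set before the data were examined.

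The alternatives were median centring and quantile normalization of the arrays, leaving out genes below the median level, averaging the probe sets of a gene, a trended robust variance, array weights, fitting only the groups compared, the replicate number as a block, leaving out each array in turn, no fold minimum, estimated list correlations, and fry. For the levels of the transduced genes every probe set was also tested separately. An alternative chosen after seeing the data left out control array 3 and estimated the list correlations together. The fits were tested on simulated data with 200 changed genes. At 2-fold, 96.5%, 96% and 95.5% of them had an adjusted p under 0.05 for the pooled lines against control, Ras against control and Src against the other oncogenes. At 1.5-fold the shares were 84%, 63% and 85%. With the 2-fold minimum as well, 50%, 42% and 50% were called at 2-fold, 0%, 1% and 0.5% at 1.5-fold and 99%, 98% and 100% at 4-fold. Without that minimum, between 2.86% and 6.37% of the calls were false. No array was left out of the main comparisons.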

Results

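RNA from mouse prostate epithelial cells of the FVB strain was measured on 15 whole-transcript arrays in 5 groups of 3. The control group held primary cultures of ventral prostate epithelium without a transduced gene. The other 4 groups held cell lines transformed with Myc, NeuT, Ras or Src. NeuT is an activated form of the receptor tyrosine kinase Erbb2, Ras a small GTPase of the growth factor pathway, Src a non-receptor tyrosine kinase and Myc a transcription factor. Values are log2 expression, with array medians from 6.19 to 6.32 over all probe sets. The 3 arrays of a group limit the precision, and no label says whether they were separate cultures, animals or lines. All p-values thus measure the spread between these samples, which may be technical. Differences among oncogenes may be traits of a line. Background was not measured here, and levels under 6.47, the median of all gene values, may lie near it. The size of fold changes with such a level on a side is thus unsure.

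Control arrays and lines also differed in culture history. The lines were grown in serum-containing medium, and the controls were kept in medium for primary prostate epithelium until the night before harvest. This difference is part of each comparison of a line group with control, and of none among the oncogenes.

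The first principal component held 30.2% of the variance and set the 3 Ras arrays (scores 55.83 to 60.33) apart from the other 12 (-24.75 to -9.88). The second held 27.1% and set the controls (-71.26 to -33.38) apart from the Myc and NeuT groups (22.96 to 28.62). Replicate arrays of the Myc, NeuT and Src groups correlated with r from 0.994 to 0.996 across genes, with 3 to 31 genes at least 2-fold apart in a pair. The Ras pairs had r from 0.980 to 0.987 and 185 to 332 such genes. These correlations are across genes, which are not independent replicates.

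**Figure D1:**
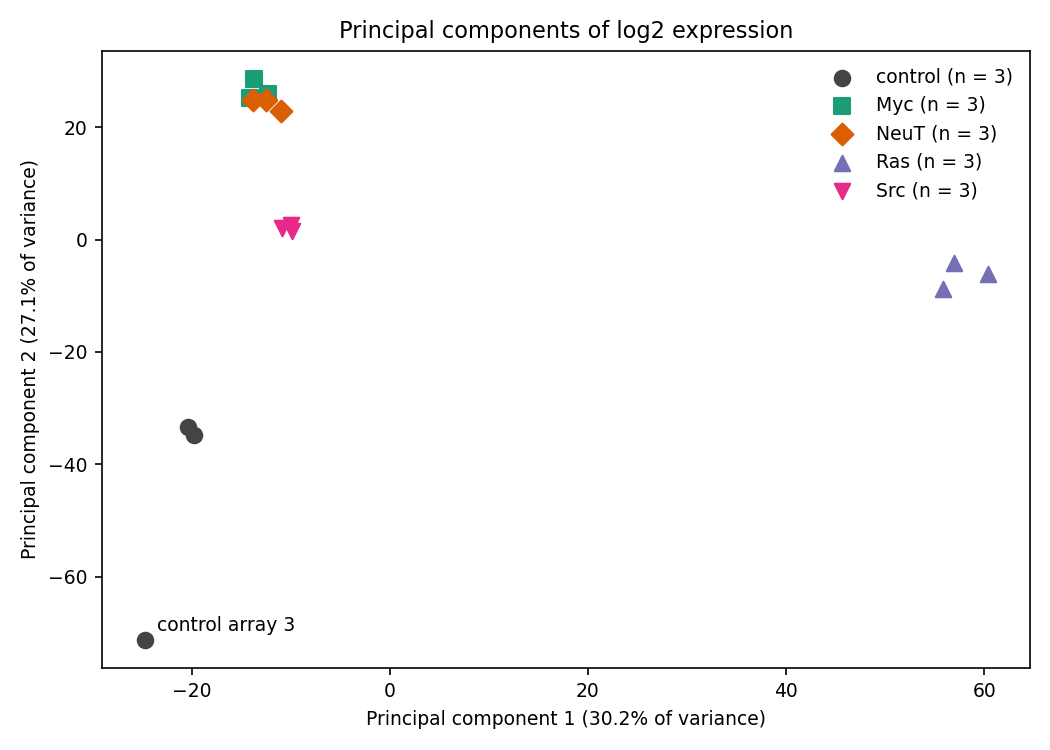
Scores of the 15 arrays on the first and second principal components of log2 expression, with 1 symbol per array and a colour and shape per group. The 3 Ras arrays lie at 55.83 to 60.33 on the first component, and control array 3 lies at -71.26 on the second, below the other controls at -34.75 and -33.38.

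Control array 3 stood apart from the other controls and carried transcripts of kidney tubules. Kap, an androgen-regulated kidney protein, was at 12.10 in this array and at a mean of 4.80 in control arrays 1 and 2. Umod, the uromodulin of the thick ascending limb, was at 11.03 against 5.70, and Slc12a1, the salt transporter of the same segment, at 9.76 against 4.54. Lrp2, the endocytic receptor megalin of the proximal tubule, was at 10.46 against 5.44. Xist, the RNA of the inactive X chromosome in female cells, was at 9.59 against 4.75. Control arrays 1 and 2 correlated with r = 0.997 across genes and had 3 genes at least 2-fold apart, while control array 3 had 682 and 709 such genes against them. In all, 685 genes were at least 2-fold higher in control array 3 than the mean of the other controls, and 2 were lower. Basal epithelial markers were lower in this array by a median log2 difference of -0.56, mitotic genes by -0.54, epithelial junction and identity genes by -0.36 and the Y-linked genes by -0.62. Endothelial markers were higher by a median of 0.64, with 5 of 12 at least 2-fold higher.

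**Figure D2:**
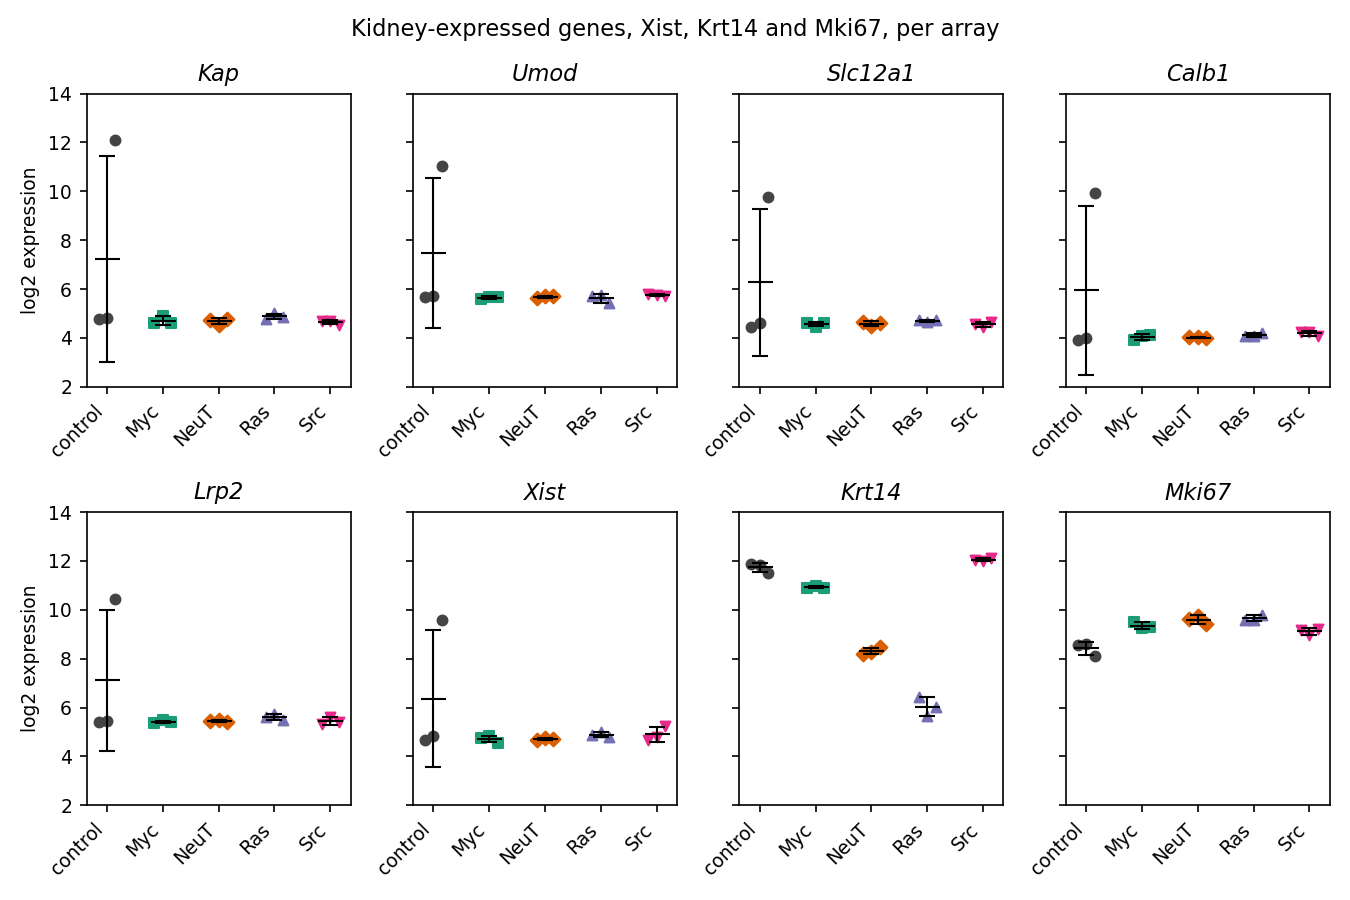
Log2 expression per array (symbols) with group mean and SD (bars, n = 3) for 5 kidney-expressed genes, Xist, the basal keratin Krt14 and the proliferation gene Mki67 in the 5 groups. For Kap, control array 3 lies at 12.10 and the other arrays lie at 4.55 to 5.01.

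The levels of the transduced genes were read first, as a check of the labels. Erbb2 was at 9.50 ± 0.38 (SD, n = 3) in the NeuT arrays and 7.80 ± 0.03 in the controls (log2 fold change 1.70 ± 0.13, adjusted p = 4.27e-07), and was thus higher in the group labelled NeuT. Myc was lower in the arrays labelled Myc, at 8.78 ± 0.17, than in the controls, at 9.70 ± 0.29 (log2 fold change -0.92 ± 0.19, adjusted p = 0.00207). It was higher than control in the NeuT arrays (log2 fold change 1.26 ± 0.19, adjusted p = 0.000189) and the Src arrays (log2 fold change 0.77 ± 0.19, adjusted p = 0.00926). In the Ras arrays it was at 8.93 ± 0.45 (log2 fold change -0.77 ± 0.19, adjusted p = 0.00733), and that call was lost when only the groups compared were fitted (adjusted p = 0.0821). Src was at 7.08 ± 0.02 in the Src arrays and 7.04 ± 0.19 in the controls (log2 fold change 0.05 ± 0.09, adjusted p = 0.743). Hras had no probe set assigned to it alone. The Myc level thus went against the label, and Src did not pass. Copies that these probe sets do not read could leave both levels, which decide neither label. Directions drawn from the Myc, Src and Ras groups rest on the labels alone.

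The mean of the 4 oncogene groups was compared with the controls, and a change of this mean need not hold in each group. Log2 fold changes are given ± SE from limma. Prl2c5, a proliferin of the prolactin family, was at 10.48 ± 0.46 (SD, n = 12) in the lines and 5.73 ± 0.65 (n = 3) in the controls (log2 fold change 4.75 ± 0.25, adjusted p = 7.12e-09). Prkg2, a cGMP-dependent protein kinase, rose as well (log2 fold change 4.08 ± 0.12, adjusted p = 2.53e-11). Further genes that rose were Pcolce2 (3.09 ± 0.24), an enhancer of procollagen processing, Prkar2b (2.38 ± 0.17), a regulatory subunit of protein kinase A, Sh2d1b1 (2.24 ± 0.21), an SH2 adaptor at 5.40 in the arrays labelled Myc, 8.23 in NeuT and 4.64 in control, and Hmga2 (2.11 ± 0.08), a chromatin protein of embryonic cells. Efemp1, an extracellular matrix fibulin, fell furthest among the genes named by the rule (log2 fold change -5.61 ± 0.22, adjusted p = 4.93e-10). The adhesion molecule Ceacam1 (-4.73 ± 0.12), the metalloproteinase inhibitor Timp3 (-4.49 ± 0.24), the ubiquitin-like Ubd (-3.94 ± 0.14) and the GABA receptor subunit Gabrp (-3.89 ± 0.22) also fell. The Y-linked genes Eif2s3y (-4.17 ± 0.18), Uty (-3.17 ± 0.11) and Kdm5d (-2.33 ± 0.18) fell, 3 of 3 measured.

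Genes of cell division rose together, and epithelial genes fell. Mitotic genes, DNA replication genes and ribosome biogenesis genes rose in 22 of 22, 23 of 23 and 26 of 26 members, with the same counts adjusted over the list alone, and 0 of these fell. Median log2 changes were 1.12, 1.11 and 0.78, at adjusted p = 9.73e-18, 5.84e-20 and 2.88e-16, and adjusted p = 0.105, 0.0985 and 0.105 with an estimated correlation. Examples were the kinase Aurkb (1.41 ± 0.11), the DNA primase subunit Prim1 (1.85 ± 0.09) and the nucleolar pseudouridine synthase Dkc1 (1.04 ± 0.11). Basal epithelial markers, luminal and secretory prostate markers and epithelial junction and identity genes fell in 18 of 19, 8 of 18 and 24 of 29 members (18, 10 and 27 adjusted over the list alone), and 0 of these rose. Log2 medians were -1.09, -1.19 and -0.78, at adjusted p = 3.73e-15, 2.24e-06 and 7.02e-18, and adjusted p = 0.0757, 0.0126 and 0.0676 with an estimated correlation. The luminal median was -0.50 without control array 3. Members that fell were the basal keratins Krt5 (-2.78 ± 0.11) and Krt15 (-3.76 ± 0.19), the desmosomal cadherin Dsg3 (-3.29 ± 0.14), the protease Tmprss2 (-3.04 ± 0.09), the luminal keratin Krt8 (-1.82 ± 0.08), E-cadherin, encoded by Cdh1 (-2.19 ± 0.10), and Epcam (-1.48 ± 0.06). Krt5 was higher than control in the Src lines (log2 fold change 1.23), and Dsg3 was at -0.21 there. Krt8 was at 12.86 in NeuT and 12.88 in control, and Epcam at 4.44 in Ras, 9.11 to 9.83 in the other lines and 9.67 in control, so that the means of these 2 fell mostly through Ras. Control array 3 was itself lower than the other controls in basal, junction and mitotic genes, as given above. Without it the basal, luminal, junction, mitotic, DNA replication and ribosome biogenesis lists had adjusted p = 0.00214, 0.0125, 0.00299, 0.0369, 0.0145 and 0.0551 with an estimated correlation.

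Further lists passed. Ras-ERK output genes and glycolysis and hypoxia genes rose in 12 of 23 and 12 of 20 members (14 and 14 adjusted over the list alone), and 1 and 2 fell. At log2 medians of 0.36 and 0.29, camera had adjusted p = 0.000648 and 0.00344, and adjusted p = 0.0985 and 0.409 with an estimated correlation. The median of the Ras-ERK output genes was 0.24 without control array 3. Members that rose were the AP-1 subunit Fosl1 (1.82 ± 0.09) and the oxygen-dependent prolyl hydroxylases Egln3 (1.53 ± 0.14) and P4ha1 (0.98 ± 0.10). Egln3 was at 5.19 in NeuT against 6.22 in control. Smooth muscle markers, matrix protease and inhibitor genes and TGF-beta response genes fell in 7 of 12, 10 of 20 and 9 of 19 members (7, 13 and 11 adjusted over the list alone), and 1, 2 and 4 rose (1, 3 and 4 adjusted over the list alone). Camera gave adjusted p = 0.000313, 0.000606 and 0.00142 at median changes of -0.25, -0.34 and -0.34, and adjusted p = 0.105, 0.126 and 0.0985 with an estimated correlation. Members that fell were the actin Acta2 (-3.25 ± 0.21), the actin-binding Tagln (-2.98 ± 0.15) and the secreted factors Tgfb2 (-2.42 ± 0.12) and Thbs1 (-2.35 ± 0.16). Without control array 3 the Ras-ERK, matrix protease and TGF-beta lists had adjusted p = 0.0369, 0.0432 and 0.023 with an estimated correlation, and the glycolysis and smooth muscle lists 0.432 and 0.119.

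The remaining lists did not pass. The mesenchymal transition genes, fibroblast markers and leukocyte markers, of which 7 and 9 of 26, 1 and 4 of 15 and 0 and 2 of 15 rose and fell (7 and 9, 1 and 4 and 0 and 1 adjusted over the list alone), had adjusted p = 0.607, 0.0691 and 0.422. The endothelial markers, neuroendocrine markers and oxidative phosphorylation genes, of which 0 and 0 of 12, 2 and 1 of 12 and 0 and 2 of 19 rose and fell (0 and 0, 2 and 1 and 0 and 1 adjusted over the list alone), had adjusted p = 0.114, 0.706 and 0.287. The ERBB receptors and ligands, interferon response genes and MHC class I presentation genes, of which 4 and 4 of 14, 1 and 3 of 22 and 0 and 3 of 11 rose and fell (4 and 4, 1 and 3 and 0 and 3 adjusted over the list alone), had adjusted p = 0.356, 0.0773 and 0.15. Cytokine and chemokine genes, cholesterol synthesis genes and p53 target genes, of which 10 and 9 of 28, 1 and 4 of 17 and 2 and 3 of 17 rose and fell (10 and 11, 1 and 4 and 2 and 3 adjusted over the list alone), had adjusted p = 0.607, 0.368 and 0.536. The CDK inhibitor genes and immediate early and heat shock genes, of which 3 and 1 of 7 and 4 and 3 of 16 rose and fell (3 and 1 and 5 and 4 adjusted over the list alone), had adjusted p = 0.356 and 0.78.

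In total, 341 genes rose and 591 fell in the lines against control at an adjusted p under 0.05 and at least 2-fold. Of the 591 that fell, 110 were at least 2-fold higher in control array 3 than in the other controls, and of the 341 that rose, 0 were lower. Without control array 3 the count was 839 (737 of them among the 932). The matrix protease list lost its call (adjusted p = 0.0809 without dim genes, all alternatives 3.46e-05 to 0.126). Interferon response genes gained a call (adjusted p = 0.0242 with median centring, 0.00506 with array weights and 2.83e-08 without Ras array 3, all alternatives 2.83e-08 to 0.819). The MHC list gained a call (adjusted p = 0.0394 with array weights and 0.00641 without Ras array 3, all alternatives 0.00641 to 0.645). Fibroblast markers gained a call (adjusted p = 0.0284 without control array 1 and 0.0466 without Ras array 2, all alternatives 2.77e-05 to 0.772). Endothelial markers gained a call (adjusted p = 0.016 without control array 1 and 0.0267 without control array 2, all alternatives 0.016 to 0.819). Oxidative phosphorylation genes gained a call (adjusted p = 0.0284 without control array 1 and 0.0119 without control array 2, all alternatives 0.0119 to 0.819). These had adjusted p from 0.116 to 0.819 with an estimated correlation.

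**Figure D3:**
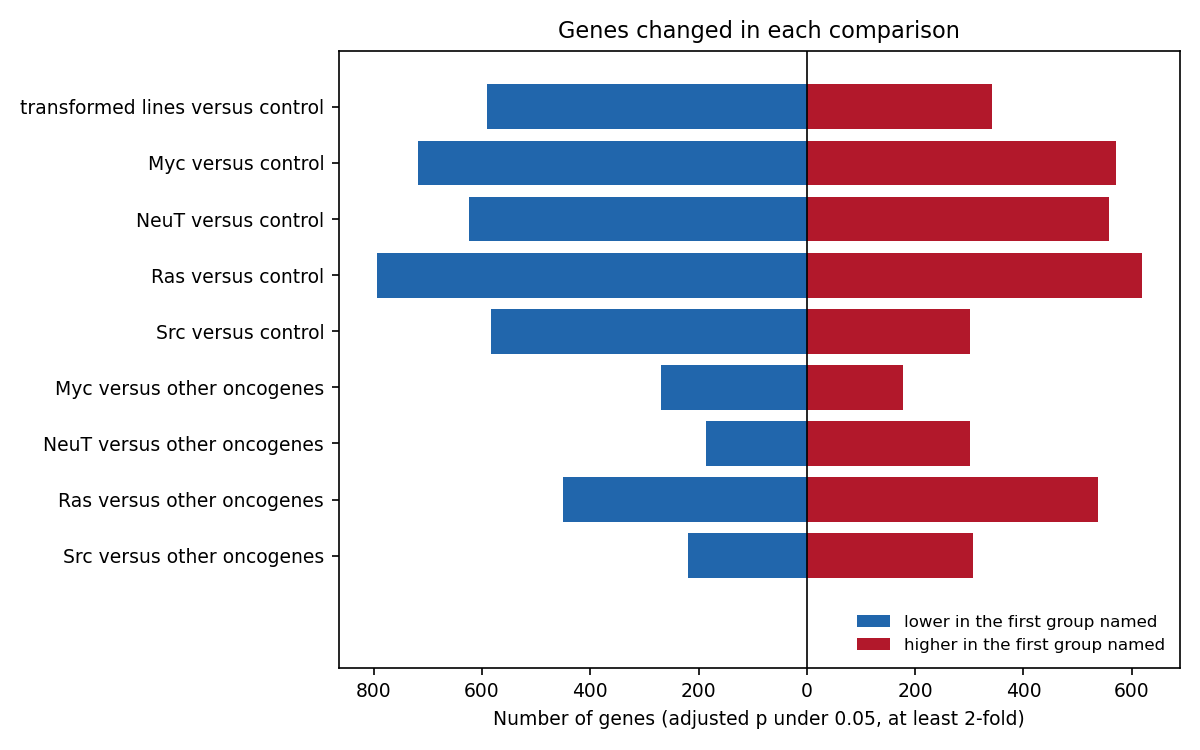
Number of genes called at an adjusted p under 0.05 and at least 2-fold in each comparison with control or with the other oncogenes, with higher expression to the right (red) and lower to the left (blue). Ras against control has 618 genes higher and 794 lower.

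In the arrays labelled Myc, compared with control, Il1a, which encodes the cytokine interleukin 1 alpha, was at 11.21 ± 0.21 (SD, n = 3) against 5.88 ± 0.46 (log2 fold change 5.32 ± 0.20, adjusted p = 6.09e-10). Other genes that rose were Prl2c5 (4.57 ± 0.31), Prkg2 (3.99 ± 0.15), the TNF receptor family member Tnfrsf26 (3.98 ± 0.28), Pate14 (3.84 ± 0.25) and the long non-coding RNA Lncenc1 (3.70 ± 0.39). Bex1, of the brain-expressed X-linked family, fell to 4.11 ± 0.32 from 10.93 ± 0.19 (log2 fold change -6.82 ± 0.22, adjusted p = 2.05e-10). Also lower were Efemp1 (-5.67 ± 0.28), Armcx3 (-5.60 ± 0.62), Ceacam1 (-5.07 ± 0.15), Timp3 (-4.72 ± 0.31) and the tetraspanin Tspan8 (-4.51 ± 0.44). The Y-linked genes fell, with Eif2s3y at -1.57 ± 0.23, Uty at -2.33 ± 0.14 and Kdm5d at -1.29 ± 0.23. Mitotic genes, DNA replication genes, ribosome biogenesis genes and cholesterol synthesis genes rose in 22 of 22, 23 of 23, 26 of 26 and 9 of 17 members, with the same counts adjusted over the list alone, and 0, 0, 0 and 1 fell. With log2 medians of 1.07, 1.19, 1.09 and 0.40, the lists had adjusted p = 5.02e-15, 1.56e-17, 6.39e-18 and 0.00684, and adjusted p = 0.127, 0.0933, 0.0933 and 0.504 with an estimated correlation. Examples were Bub1b (1.82 ± 0.18) of the spindle checkpoint, Polr1b (2.07 ± 0.18) of RNA polymerase I, and the isoprenoid enzyme Idi1 (1.57 ± 0.30).

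Basal epithelial markers, luminal and secretory prostate markers and epithelial junction and identity genes fell in 15 of 19, 6 of 18 and 12 of 29 members (15, 6 and 13 adjusted over the list alone), and 0, 0 and 2 rose (0, 0 and 3 adjusted over the list alone). The log2 medians were -1.18, -0.34 and -0.34, with adjusted p = 1.75e-12, 0.000538 and 0.000875, and adjusted p = 0.0933, 0.0902 and 0.382 with an estimated correlation. The luminal median was -0.21 without control array 3. Mesenchymal transition genes, fibroblast markers and smooth muscle markers fell in 12 of 26, 4 of 15 and 5 of 12 members (13, 3 and 6 adjusted over the list alone), and 1, 0 and 0 rose. Median changes of -0.45, -0.11 and -0.30 (log2) had adjusted p = 8.58e-05, 0.00913 and 0.0002, and adjusted p = 0.0933, 0.0933 and 0.0933 with an estimated correlation. Matrix protease and inhibitor genes, TGF-beta response genes and interferon response genes fell in 9 of 20, 9 of 19 and 4 of 22 members (9, 9 and 3 adjusted over the list alone), and 0, 1 and 1 rose. By camera, the lists had adjusted p = 8.58e-05, 0.00145 and 0.0124 at medians of -0.42, -0.39 and -0.59 (log2), and adjusted p = 0.0933, 0.0933 and 0.793 with an estimated correlation. Genes that fell included Krt17 (-3.54 ± 0.17), the matrix protein Tnc (-4.36 ± 0.17), Snai2 (-2.71 ± 0.13), Vim (-1.57 ± 0.09), Acta2 (-4.07 ± 0.26), Tgfb2 (-2.86 ± 0.15) and Ifit2 (-2.54 ± 0.11). In this group 570 genes rose and 718 fell, and the other 12 lists did not pass (adjusted p from 0.0888 to 0.936). Of the 718, 104 were higher in control array 3 by at least 2-fold, and without that array 1236 (1102 of them among the 1288) genes were called. Fibroblast markers lost their call (adjusted p = 0.695 without dim genes, all alternatives 6.91e-06 to 0.695). Oxidative phosphorylation genes gained a call (adjusted p = 0.0277 with array weights and 0.00636 without control array 3 (0.2 with an estimated correlation), all alternatives 0.00636 to 0.992). This list had adjusted p = 0.982 with an estimated correlation. With an estimated correlation and without control array 3, the basal, luminal, DNA replication, matrix protease and TGF-beta lists alone passed (adjusted p = 0.00455, 0.0389, 0.0389, 0.0389 and 0.0389).

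In the NeuT lines, Il1a rose as well (log2 fold change 4.96 ± 0.20, adjusted p = 8.8e-10), as did Gap43, a growth cone protein of neurons, at 11.03 ± 0.11 (SD, n = 3) against 6.29 ± 0.10 (log2 fold change 4.75 ± 0.18, adjusted p = 6.58e-10). Cpa4, a carboxypeptidase (4.46 ± 0.27), Pate14 (4.40 ± 0.25), Prl2c5 (4.36 ± 0.31) and Lncenc1 (4.18 ± 0.39) followed. The basal keratin Krt5 fell to 5.70 ± 0.07 from 10.96 ± 0.34 (log2 fold change -5.26 ± 0.14, adjusted p = 6.84e-11), with Dsg3 (-5.07 ± 0.18) and Krt14 (-3.42 ± 0.15). Efemp1 (-5.80 ± 0.28), Ceacam1 (-5.15 ± 0.15), Timp3 (-4.81 ± 0.31) and the Y-linked Eif2s3y (-5.16 ± 0.23), Uty (-3.48 ± 0.14) and Kdm5d (-2.67 ± 0.23) fell too. Mitotic genes, DNA replication genes, ribosome biogenesis genes and Ras-ERK output genes rose in 22 of 22, 23 of 23, 24 of 26 and 13 of 23 members (22, 23, 24 and 15 adjusted over the list alone), and 0 of these fell. Median log2 changes were 1.35, 1.25, 0.98 and 0.48, at adjusted p = 1.22e-18, 1.65e-18, 5.79e-16 and 1.3e-06, and adjusted p = 0.128, 0.128, 0.138 and 0.0775 with an estimated correlation. Members that rose were the mitotic kinase Plk1 (1.88 ± 0.13), Mcm2 (1.25 ± 0.10), Fosl1 (2.42 ± 0.12), cyclin D1, encoded by Ccnd1 (1.42 ± 0.11), and the cytokine Lif (1.68 ± 0.18).

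Basal epithelial markers, luminal and secretory prostate markers and epithelial junction and identity genes fell in 12 of 19, 4 of 18 and 14 of 29 members (13, 4 and 15 adjusted over the list alone), and 1, 0 and 4 rose. Log2 medians were -1.38, -0.09 and -0.29, at adjusted p = 7e-10, 0.00686 and 0.00178, and adjusted p = 0.128, 0.128 and 0.395 with an estimated correlation. The luminal median was -0.18 without control array 1 and -0.05 without NeuT array 2. Fibroblast markers and smooth muscle markers fell in 4 of 15 and 5 of 12 members (4 and 7 adjusted over the list alone), and 1 and 1 rose. At log2 medians of -0.09 and -0.28, camera had adjusted p = 0.0317 and 0.00128, and adjusted p = 0.128 and 0.138 with an estimated correlation. MHC class I presentation genes, matrix protease and inhibitor genes and TGF-beta response genes fell in 5 of 11, 7 of 20 and 8 of 19 members (7, 8 and 8 adjusted over the list alone), and 0, 0 and 3 rose. Camera gave adjusted p = 0.00138, 0.00045 and 0.0114 at median changes of -0.41, -0.35 and -0.15, and adjusted p = 0.243, 0.138 and 0.138 with an estimated correlation. For the TGF-beta response genes the median was -0.10 without control array 1. Members that fell included Tmprss2 (-3.02 ± 0.12), Ocln (-1.11 ± 0.13), Tagln (-2.94 ± 0.19), Erap1 (-1.54 ± 0.22) and Id2 (-2.81 ± 0.36). A total of 558 genes rose and 624 fell (633 and 567 with median centring), and the other 13 lists did not pass (adjusted p from 0.0516 to 0.85). Among the 624, 99 were at least 2-fold higher in control array 3, and 1105 (990 of them among the 1182) genes were called without it. Fibroblast markers lost their call (adjusted p = 0.057 with quantile normalization, 0.939 without dim genes, 0.0517 with array weights and 0.0686 without control array 3, all alternatives 5.92e-05 to 0.939). Interferon response genes gained a call (adjusted p = 0.0198 with median centring, 0.0454 with quantile normalization, 0.048 without dim genes, 0.0481 with probe sets averaged, 0.00903 with array weights, 8.2e-06 with the compared groups alone, 0.0478 with the replicate block, 0.04 without Ras array 1, 0.0302 without Ras array 2 and 8.84e-06 without Ras array 3, all alternatives 8.2e-06 to 0.776). The cytokine list gained a call (adjusted p = 0.04999 with median centring, all alternatives 0.04999 to 0.613). The glycolysis list gained a call (adjusted p = 0.0164 with probe sets averaged, 0.014 with array weights, 0.0411 with the compared groups alone, 0.0293 without control array 3 (0.55 with an estimated correlation), 0.0341 without NeuT array 1, 0.0491 without NeuT array 3, 0.0302 without Ras array 2 and 0.049 without Ras array 3, all alternatives 0.014 to 0.581). Endothelial markers gained a call (adjusted p = 0.0213 without control array 1 and 0.0354 without control array 2, all alternatives 0.0213 to 0.952). These had adjusted p from 0.581 to 0.686 with an estimated correlation. When control array 3 was left out, the basal, mitotic, DNA replication, Ras-ERK and matrix protease lists alone passed with an estimated correlation (adjusted p = 0.00886, 0.047, 0.0268, 0.00939 and 0.047).

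The Ras lines lost keratins and epithelial adhesion genes. Krt7, a keratin of simple epithelia, was at 5.76 ± 0.01 (SD, n = 3) against 12.08 ± 0.15 in control (log2 fold change -6.32 ± 0.08, adjusted p = 4.22e-15), and the basal keratin Krt14 at 6.04 ± 0.38 against 11.73 ± 0.20 (log2 fold change -5.69 ± 0.15, adjusted p = 5.14e-12). Further genes that fell were Bex1 (-7.13 ± 0.22), the secreted chaperone Clu (-5.93 ± 0.26), Mal2 (-5.84 ± 0.18) of apical transport and S100a14 (-5.67 ± 0.10). Nefm, a neurofilament subunit, rose to 10.17 ± 0.74 from 4.39 ± 0.14 (log2 fold change 5.77 ± 0.25, adjusted p = 4.92e-10). The lipase family member Lipn (5.67 ± 0.24), Prl2c5 (4.86 ± 0.31), the sialomucin Cd34 (4.82 ± 0.27), the complement receptor C3ar1 (4.71 ± 0.20) and Prkg2 (4.41 ± 0.15) rose as well. The Y-linked genes fell, with Eif2s3y at -5.06 ± 0.23, Uty at -3.37 ± 0.14 and Kdm5d at -2.60 ± 0.23.

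Basal epithelial markers, luminal and secretory prostate markers and epithelial junction and identity genes fell in 17 of 19, 10 of 18 and 28 of 29 members, with the same counts adjusted over the list alone, and 1, 0 and 0 rose. With log2 medians of -2.68, -1.80 and -2.27, the lists had adjusted p = 1.21e-18, 1.37e-08 and 4.48e-31, and adjusted p = 0.0379, 0.00338 and 0.0103 with an estimated correlation. The luminal median was -1.19 without control array 3. Members that fell included Krt5 (-5.37 ± 0.14), Krt8 (-5.29 ± 0.10), Epcam (-5.23 ± 0.08), Cdh1 (-5.25 ± 0.13) and the epithelial splicing factor Esrp1 (-4.80 ± 0.15). Mesenchymal transition genes rose in 10 of 26 members, with the same counts adjusted over the list alone, and 4 fell. The log2 median was 0.15, with adjusted p = 0.00378, and adjusted p = 0.236 with an estimated correlation. For the mesenchymal transition genes the median was 0.25 without Ras array 3. N-cadherin, encoded by Cdh2 (3.77 ± 0.10), Vim (2.99 ± 0.09), S100a4 (2.82 ± 0.15) and the transcription factor Twist1 (2.38 ± 0.13) rose. Smooth muscle markers and cholesterol synthesis genes fell in 6 of 12 and 10 of 17 members (8 and 11 adjusted over the list alone), and 1 and 0 rose (1 and 1 adjusted over the list alone). Median changes of -0.28 and -0.64 (log2) had adjusted p = 0.00102 and 5.62e-05, and adjusted p = 0.176 and 0.28 with an estimated correlation. P53 target genes and TGF-beta response genes fell in 6 of 17 and 11 of 19 members (6 and 11 adjusted over the list alone), and 0 and 2 rose (0 and 3 adjusted over the list alone). By camera, the lists had adjusted p = 0.00196 and 0.000217 at medians of -0.35 and -0.57 (log2), and adjusted p = 0.412 and 0.073 with an estimated correlation. The median of the p53 target genes was -0.10 without Ras array 2. Examples were the sterol synthesis enzyme Hmgcs1 (-1.56 ± 0.24), the apoptosis gene Pmaip1 (-2.05 ± 0.16), Thbs1 (-4.57 ± 0.20) and the activin subunit Inhba (-4.15 ± 0.34).

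Mitotic genes and DNA replication genes rose in 22 of 22 and 23 of 23 members, with the same counts adjusted over the list alone, and 0 of these fell. Median log2 changes were 1.14 and 1.03, at adjusted p = 2.08e-16 and 1.04e-16, and adjusted p = 0.155 and 0.119 with an estimated correlation. Ribosome biogenesis genes, Ras-ERK output genes and glycolysis and hypoxia genes rose in 13 of 26, 13 of 23 and 9 of 20 members (14, 14 and 10 adjusted over the list alone), and 0, 4 and 2 fell. Log2 medians were 0.42, 0.41 and 0.34, at adjusted p = 9.48e-05, 0.000567 and 0.00326, and adjusted p = 0.463, 0.0954 and 0.412 with an estimated correlation. For the ribosome biogenesis genes the median was 0.27 without control array 3. The mitotic kinesin Kif20a (1.52 ± 0.14), the ETS factor Etv1 (3.82 ± 0.37), the feedback inhibitor Spry2 (1.30 ± 0.11) and Egln3 (3.18 ± 0.18) were among those that rose. Against control, 618 genes rose and 794 fell in the Ras lines, and the other 12 lists did not pass (adjusted p from 0.128 to 0.899). Of the 794, 95 were at least 2-fold higher in control array 3, and 1372 (1244 of them among the 1412) genes were called without that array. Interferon response genes had a median of 1.66 over the control mean in Ras array 3 and of -0.39 and -0.45 in Ras arrays 1 and 2. Oxidative phosphorylation genes gained a call (adjusted p = 0.0136 without control array 1 and 0.00591 without control array 2, all alternatives 0.00591 to 0.968). Interferon response genes gained a call (adjusted p = 0.0262 without Ras array 1, 0.016 without Ras array 2 and 4.99e-05 without Ras array 3, all alternatives 4.99e-05 to 0.922). The MHC list gained a call (adjusted p = 0.0137 without Ras array 3, all alternatives 0.0137 to 0.948). They had adjusted p from 0.809 to 0.857 with an estimated correlation. With an estimated correlation and without control array 3, the basal, luminal, junction, DNA replication, Ras-ERK and TGF-beta lists alone passed (adjusted p = 0.000664, 0.00491, 0.000664, 0.0262, 0.0313 and 0.0156). The interferon median was 0.20 with all arrays and -0.47 without Ras array 3, so that its direction turned.

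**Figure D4:**
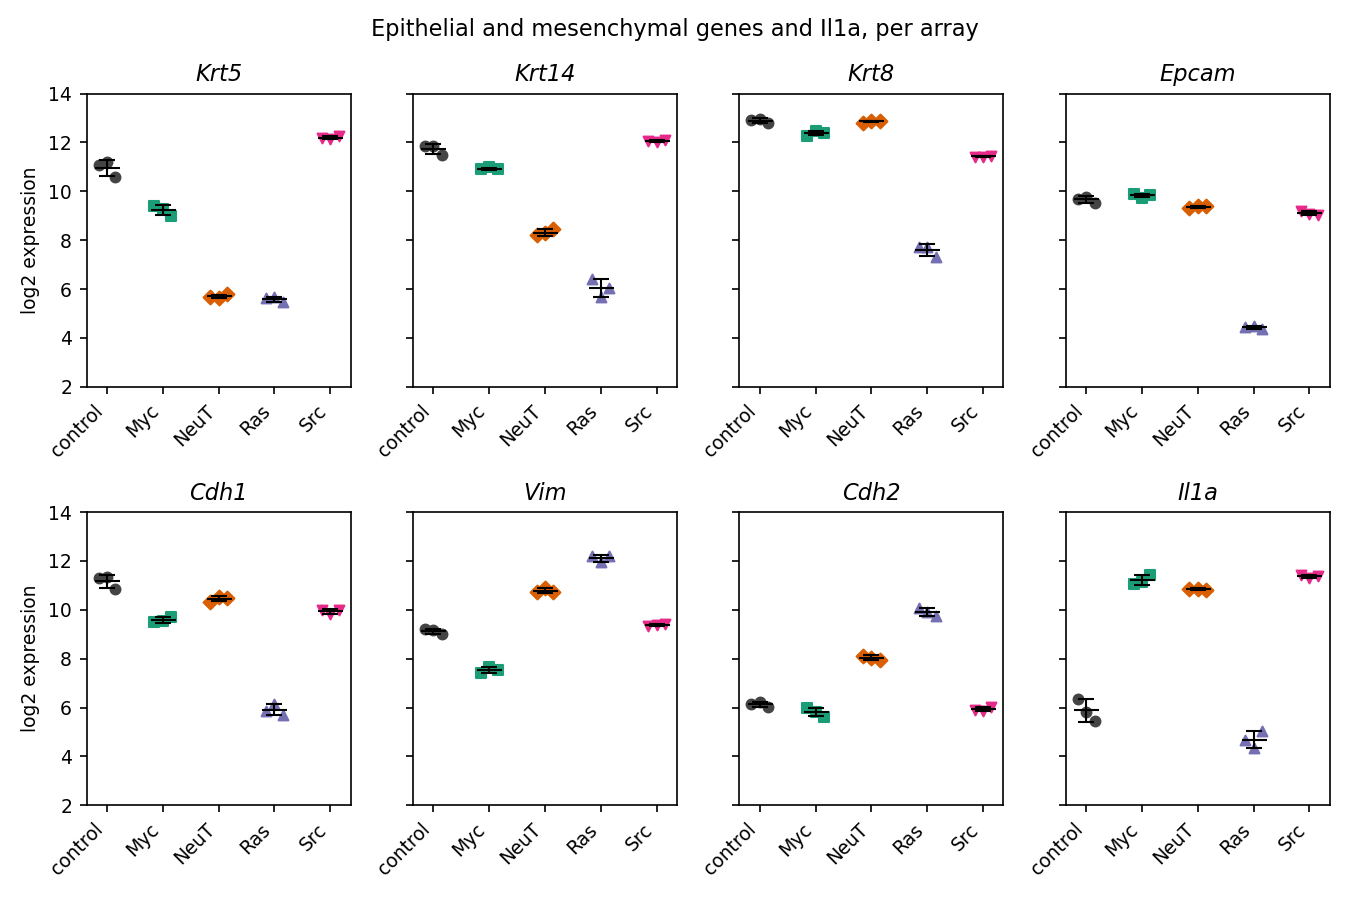
Log2 expression per array (symbols) with group mean and SD (bars, n = 3) for epithelial genes, mesenchymal genes and Il1a in the 5 groups. Krt8 is at 7.59 in the Ras group and at 11.42 to 12.89 in the other groups.

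The basal keratin Krt5 was higher in the Src lines, at 12.19 ± 0.06 (SD, n = 3) against 10.96 ± 0.34 in control (log2 fold change 1.23). Il1a rose (log2 fold change 5.49 ± 0.20, adjusted p = 3.62e-10), and so did Il1f9, which encodes an interleukin 1 family cytokine of epithelia, at 10.50 ± 0.21 against 5.61 ± 0.15 (log2 fold change 4.89 ± 0.40, adjusted p = 8.78e-07). Prl2c5 (5.19 ± 0.31), the receptor phosphatase Ptprz1 (4.59 ± 0.23), Tmem45a (4.23 ± 0.35) and Prkg2 (4.22 ± 0.15) also rose. Bex1 (-6.50 ± 0.22), Efemp1 (-5.57 ± 0.28), the zinc finger gene Zbtb10 (-4.76 ± 0.18), Timp3 (-4.32 ± 0.31) and Ceacam1 (-4.27 ± 0.15) fell, as did the Y-linked Eif2s3y (-4.91 ± 0.23), Uty (-3.52 ± 0.14) and Kdm5d (-2.77 ± 0.23). Mitotic genes and DNA replication genes rose in 18 of 22 and 23 of 23 members (19 and 23 adjusted over the list alone), and 0 of these fell. At log2 medians of 0.72 and 1.09, camera had adjusted p = 1.53e-09 and 4.66e-18, and adjusted p = 0.346 and 0.185 with an estimated correlation. Ribosome biogenesis genes and glycolysis and hypoxia genes rose in 24 of 26 and 10 of 20 members (25 and 13 adjusted over the list alone), and 0 and 2 fell (0 and 4 adjusted over the list alone). Camera gave adjusted p = 1.28e-11 and 0.00538 at median changes of 0.70 and 0.30, and adjusted p = 0.249 and 0.496 with an estimated correlation. Members that rose included Kif11 (1.71 ± 0.18), Egln3 (3.10 ± 0.18) and the glycolytic Pfkp (1.58 ± 0.19).

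Basal epithelial markers did not pass as a list in the Src lines (adjusted p = 0.592): 6 of 19 rose and 5 fell (8 and 5 adjusted over the list alone), with Trp63 (1.73 ± 0.12), the p63 transcription factor of basal cells, higher and Krt15 (-2.42 ± 0.24) lower. Luminal and secretory prostate markers, epithelial junction and identity genes and smooth muscle markers fell in 5 of 18, 17 of 29 and 5 of 12 members (7, 18 and 5 adjusted over the list alone), and 3, 1 and 0 rose (3, 1 and 1 adjusted over the list alone). With log2 medians of -0.10, -0.37 and -0.20, the lists had adjusted p = 0.034, 8.4e-09 and 0.00361, and adjusted p = 0.185, 0.185 and 0.249 with an estimated correlation. The luminal median was -0.05 without control array 3. Matrix protease and inhibitor genes, cholesterol synthesis genes and interferon response genes fell in 10 of 20, 6 of 17 and 3 of 22 members (12, 8 and 2 adjusted over the list alone), and 3, 0 and 1 rose. The log2 medians were -0.41, -0.32 and -0.57, with adjusted p = 6.02e-05, 0.00538 and 0.027, and adjusted p = 0.185, 0.541 and 0.795 with an estimated correlation. The claudins Cldn7 (-2.82 ± 0.20) and Cldn6 (-1.70 ± 0.17), Ocln (-1.54 ± 0.13), Pmvk (-0.52 ± 0.12) and Ifit2 (-1.10 ± 0.11) were among those that fell. In all, 302 genes rose and 584 fell, and the other 15 lists did not pass (adjusted p from 0.0505 to 0.711). Of the 584, 88 were at least 2-fold higher in control array 3, without which 870 (746 of them among the 886) genes were called. The luminal list lost its call (adjusted p = 0.208 without dim genes, 0.0717 with array weights, 0.0667 with the compared groups alone and 0.0526 without control array 3, all alternatives 2.31e-05 to 0.249). Cholesterol synthesis genes lost their call (adjusted p = 0.067 without dim genes, all alternatives 0.000459 to 0.541). The matrix protease list lost its call (adjusted p = 0.0518 without dim genes, all alternatives 8.49e-06 to 0.185). Fibroblast markers gained a call (adjusted p = 0.048 with median centring, 0.0426 with quantile normalization, 0.0226 without control array 1, 0.0447 without control array 2, 0.0476 without NeuT array 2, 0.0437 without Ras array 1, 0.0452 without Ras array 2 and 0.0355 without Src array 2, all alternatives 0.000134 to 0.832). Ras-ERK output genes gained a call (adjusted p = 0.0281 with quantile normalization, 0.0255 without dim genes, 0.0207 without control array 1, 0.0447 without control array 2 and 0.0323 without Src array 2, all alternatives 0.000171 to 0.346). Endothelial markers gained a call (adjusted p = 0.0246 without control array 1 and 0.0443 without control array 2, all alternatives 0.0246 to 0.964). Oxidative phosphorylation genes gained a call (adjusted p = 0.016 without control array 1 and 0.00623 without control array 2, all alternatives 0.00623 to 0.861). These had adjusted p from 0.185 to 0.795 with an estimated correlation. When control array 3 was left out, the junction and DNA replication lists alone passed with an estimated correlation (adjusted p = 0.0428 and 0.0428).

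**Figure D5:**
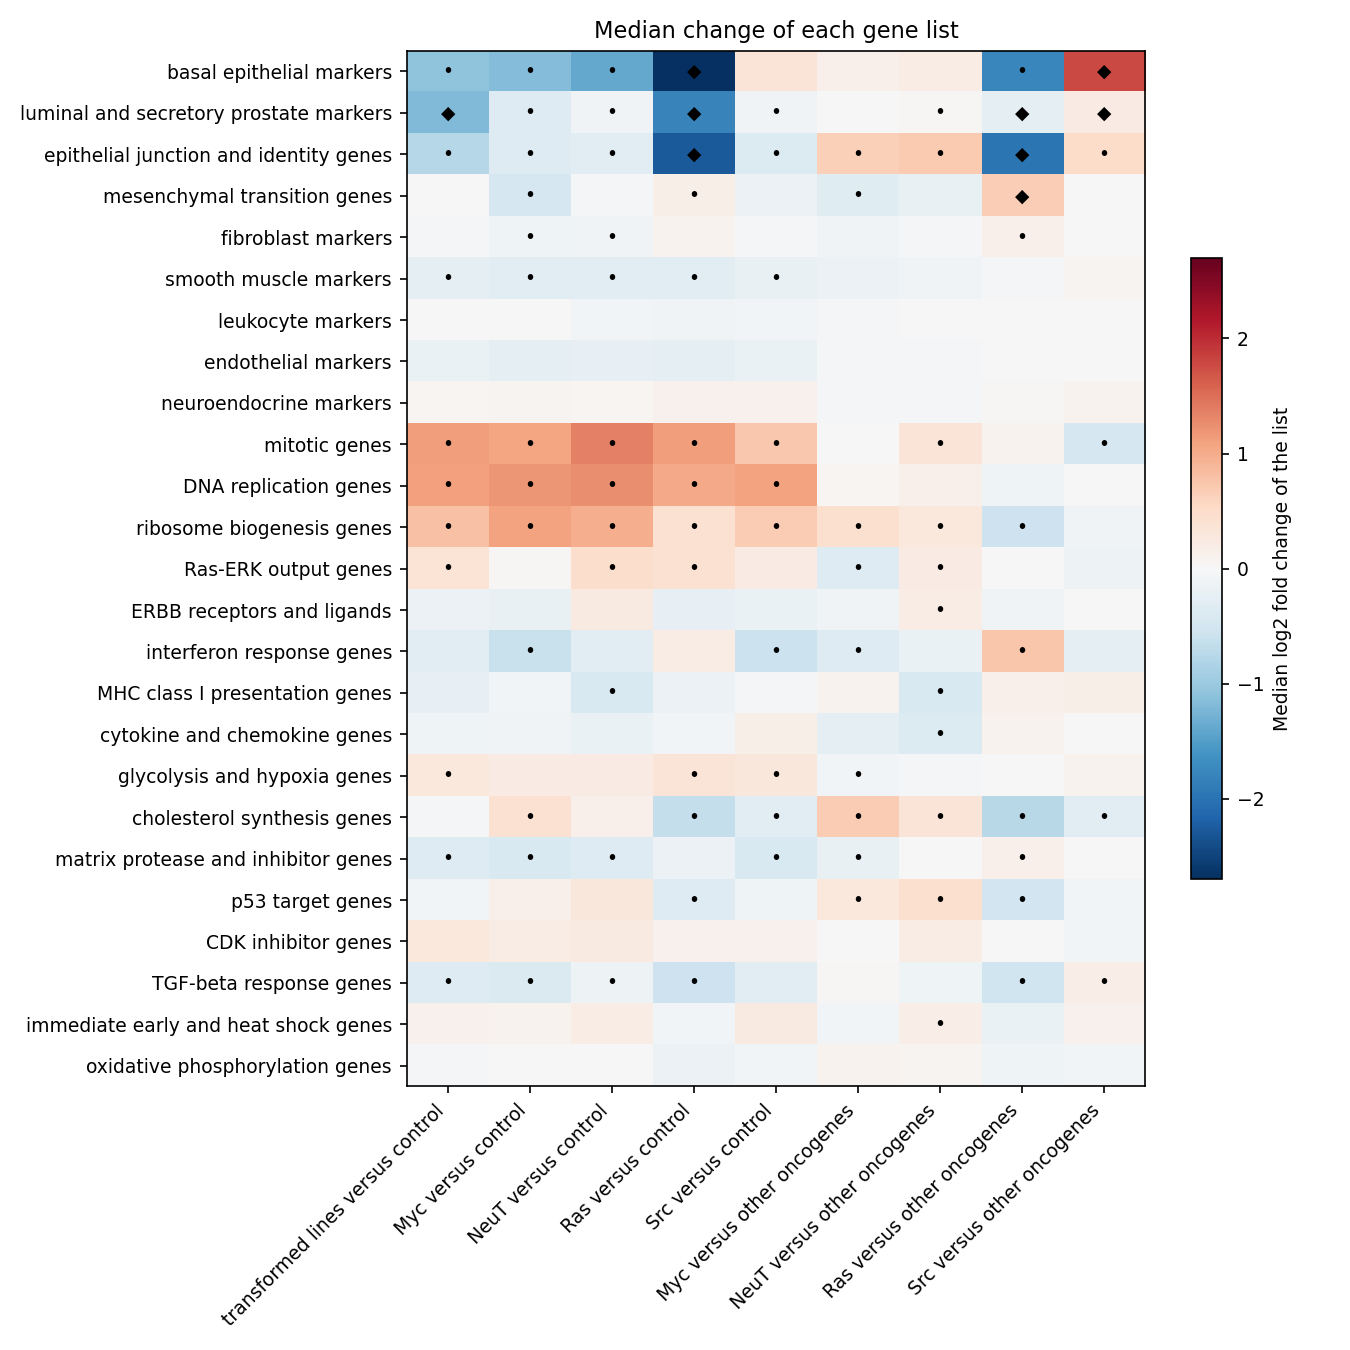
Median log2 fold change of the measured members of each gene list (vertical) in each comparison (horizontal), on a colour scale from blue (lower) to red (higher). Dots stand for lists called with the preset correlation and diamonds for those also called with an estimated one, such as the epithelial junction and identity genes in Ras against control, at -2.27.

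Changes against control shared by the 4 oncogenes were counted next. Prkg2 rose in each group, with log2 fold changes from 3.69 to 4.41, and Ceacam1 fell in each. In the same direction, 82 genes rose and 187 fell in all 4 groups, 269 in total. Independent lists of these sizes would share 0.00749 and 0.0262 genes, and 100 simulations that placed each group's changes on genes at random, against shared controls, shared a mean of 0.59 and at most 3. These simulations were chosen after seeing the data and hold no bias of the control arrays. Part of the excess may come from the control arrays, which all 4 comparisons share. Without control array 3 the count was 234 (53 rose and 181 fell), 200 of them among the 269.

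Among the 4 oncogene groups, whose lines were cultured alike, 2237 genes differed by the F test with a range of at least 1 on the log2 scale between group means. Pairs with Ras differed in the most genes: 1227 between the arrays labelled Myc and Ras (610 higher in the former and 617 lower), 1191 between NeuT and Ras (657 and 534, or 548 and 591 with quantile normalization) and 1094 between Ras and Src (589 and 505). The pairs without Ras differed in 463 genes for Myc against NeuT (162 and 301), 619 for Myc against Src (273 and 346) and 709 for NeuT against Src (394 and 315).

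Each oncogene was then set against the mean of the other 3, which leaves the control arrays out of the contrast but can differ through 1 of the 3. In the arrays labelled Myc, whose Myc level was the lowest of the line groups, Gatm, an enzyme of creatine synthesis, was at 10.53 ± 0.09 (SD, n = 3) against 6.55 ± 1.40 (n = 9) in the other lines (log2 fold change 3.98 ± 0.73, adjusted p = 0.00119). Adtrp (3.85 ± 0.60), the Y-linked Eif2s3y (3.47 ± 0.19), Uty (1.12 ± 0.12) and Kdm5d (1.39 ± 0.19), the nuclear receptor Nr1h5 (3.17 ± 0.28), the mannose receptor Mrc1 (2.56 ± 0.13) and Mia2 (2.44 ± 0.16) were higher. Caveolin 1, encoded by Cav1, was at 5.37 ± 0.16 against 9.94 ± 0.40 (log2 fold change -4.57 ± 0.17, adjusted p = 8.17e-10). Tnc (-3.91 ± 0.14), the carbonic anhydrase Car13 (-3.50 ± 0.17), Armcx3 (-3.47 ± 0.51), Vim (-3.21 ± 0.08) and the fatty acid desaturase Scd1 (-3.14 ± 0.31) were lower. The junction, ribosome, cholesterol and p53 lists rose in 21 of 29, 14 of 26, 13 of 17 and 7 of 17 members. Adjusted over the list alone these were 22, 19, 16 and 9, and 0, 0, 1 and 1 fell. Median changes of 0.64, 0.43, 0.69 and 0.29 (log2) had adjusted p = 2.25e-15, 5.28e-09, 6.78e-09 and 0.00533, and adjusted p = 0.0665, 0.453, 0.207 and 0.521 with an estimated correlation. Members that were higher included Epcam (2.19 ± 0.06), Polr1b (1.11 ± 0.14), Idi1 (1.82 ± 0.25) and Mdm2 (0.75 ± 0.16). Against NeuT, Ras and Src singly the medians were -0.07, 1.81 and 0.15 for the junction and 0.04, 0.78 and 0.22 for the p53 list. Both rose mainly through Ras.

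The mesenchymal, Ras-ERK and matrix protease lists fell in 11 of 26, 13 of 23 and 7 of 20 members. Adjusted over the list alone these were 11, 14 and 9, and 0, 2 and 2 rose. By camera, the lists had adjusted p = 5.28e-09, 4.74e-06 and 0.0161 at medians of -0.32, -0.34 and -0.19 (log2), and adjusted p = 0.0526, 0.0526 and 0.467 with an estimated correlation. For the mesenchymal transition genes the median was -0.21 without Ras array 2. Interferon response genes and glycolysis and hypoxia genes fell in 3 of 22 and 5 of 20 members, with the same counts adjusted over the list alone, and 1 and 0 rose. Median log2 changes were -0.34 and -0.08, at adjusted p = 0.0277 and 0.0161, and adjusted p = 0.78 and 0.521 with an estimated correlation. Without Ras array 3 the interferon and glycolysis medians were -0.11 and -0.05. Cdh2 (-2.15 ± 0.08), Snai2 (-2.78 ± 0.11), the ERK phosphatase Dusp6 (-1.47 ± 0.10), the collagenase Mmp13 (-2.89 ± 0.20), Ifit2 (-2.31 ± 0.09) and Pfkp (-1.67 ± 0.16) were lower. In this contrast 178 genes were higher and 270 lower, and the other 16 lists did not pass (adjusted p from 0.0714 to 1). Interferon response genes lost their call (adjusted p = 0.0883 without dim genes, 0.0508 without array 2 labelled Myc and 0.0731 without Ras array 3, all alternatives 0.00293 to 0.78). P53 target genes lost their call (adjusted p = 0.0883 without dim genes, all alternatives 0.000962 to 0.521). Fibroblast markers gained a call (adjusted p = 0.0411 with array weights, 0.0498 with the compared groups alone and 0.0492 without control array 3 (0.213 with an estimated correlation), all alternatives 0.00179 to 0.444). Oxidative phosphorylation genes gained a call (adjusted p = 0.031 with array weights, 0.0122 with the compared groups alone and 0.0123 without control array 3 (0.332 with an estimated correlation), all alternatives 0.0122 to 0.79). The cytokine list gained a call (adjusted p = 0.0374 without Ras array 2, all alternatives 0.0374 to 0.78). Smooth muscle markers gained a call (adjusted p = 0.0469 without Ras array 3, all alternatives 0.0423 to 0.521). They had adjusted p from 0.207 to 0.79 with an estimated correlation. With an estimated correlation and without control array 3, the junction, mesenchymal and Ras-ERK lists alone passed (adjusted p = 0.00989, 0.0246 and 0.00989).

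In the NeuT lines, Bex1 was at 10.67 ± 0.19 (SD, n = 3) against 4.11 ± 0.42 (n = 9) in the other lines (log2 fold change 6.55 ± 0.18, adjusted p = 5.19e-11), near its level of 10.93 ± 0.19 in control. The membrane metallopeptidase neprilysin, encoded by Mme, was at 10.83 ± 0.16 against 5.24 ± 0.41 (log2 fold change 5.60 ± 0.64, adjusted p = 2.53e-05). Gap43 (3.93 ± 0.15), Tnc (3.75 ± 0.14), Cpa4 (3.38 ± 0.22) and Slc43a3 (3.33 ± 0.57) were also higher. Lower genes were Egln3 (-3.41 ± 0.15), Mmp13 (-3.33 ± 0.20), the proteoglycan Vcan (-3.32 ± 0.17), the chemokine Ccl2 (-3.29 ± 0.12) and Ifitm3 (-3.15 ± 0.12). Of the Y-linked genes, Eif2s3y (-1.31 ± 0.19) and Uty (-0.41 ± 0.12) were lower, and Kdm5d was at -0.45 (adjusted p = 0.119). These differences came from the arrays labelled Myc: Eif2s3y was at 6.96 there and at 3.37, 3.47 and 3.62 in NeuT, Ras and Src. ERBB receptors and ligands and Ras-ERK output genes rose in 5 of 14 and 10 of 23 members (5 and 13 adjusted over the list alone), and 0 and 3 fell. Log2 medians were 0.21 and 0.22, at adjusted p = 0.00219 and 0.000399, and adjusted p = 0.124 and 0.124 with an estimated correlation. Erbb2 (1.74 ± 0.11), its partner receptor Erbb3 (1.49 ± 0.14), Ccnd1 (1.16 ± 0.09) and Lif (1.76 ± 0.15) were higher.

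Luminal and secretory prostate markers, epithelial junction and identity genes and mitotic genes rose in 6 of 18, 22 of 29 and 11 of 22 members (8, 22 and 12 adjusted over the list alone), and 1, 1 and 0 fell (1, 2 and 0 adjusted over the list alone). At log2 medians of 0.04, 0.72 and 0.34, camera had adjusted p = 0.0349, 2.17e-16 and 0.00017, and adjusted p = 0.218, 0.124 and 0.636 with an estimated correlation. The luminal median was 0.03 without array 3 labelled Myc, 0.07 without NeuT array 1, -0.0047 without NeuT array 2, 0.02 without Ras array 2 and 0.07 without Ras array 3. Ribosome biogenesis genes and cholesterol synthesis genes rose in 11 of 26 and 7 of 17 members (14 and 9 adjusted over the list alone), and 3 and 0 fell (3 and 1 adjusted over the list alone). Camera gave adjusted p = 0.00607 and 0.000416 at median changes of 0.29 and 0.34, and adjusted p = 0.673 and 0.505 with an estimated correlation. P53 target genes and immediate early and heat shock genes rose in 9 of 17 and 5 of 16 members (9 and 7 adjusted over the list alone), and 1 and 1 fell. With log2 medians of 0.44 and 0.17, the lists had adjusted p = 0.00308 and 0.0153, and adjusted p = 0.574 and 0.43 with an estimated correlation. Krt8 (2.39 ± 0.08), Plk1 (1.04 ± 0.11), the death receptor Tnfrsf10b (0.90 ± 0.20) and the phosphatase Dusp1 (1.88 ± 0.08) were among the higher members. Krt8 was at 12.86 in NeuT, 12.39 in the arrays labelled Myc, 11.42 in Src and 7.59 in Ras. Against Myc, Ras and Src singly the medians were 0.07, 2.08 and 0.15 for the junction list, so that it rose mainly through Ras, 0.01, 0.24 and -0.08 for the luminal, -0.11, 0.73 and 0.34 for the ribosome, -0.30, 0.89 and 0.41 for the cholesterol and -0.04, 0.70 and 0.32 for the p53 list. MHC class I presentation genes and cytokine and chemokine genes fell in 5 of 11 and 12 of 28 members (6 and 15 adjusted over the list alone), and 0 and 8 rose. The log2 medians were -0.41 and -0.37, with adjusted p = 0.000528 and 0.0279, and adjusted p = 0.395 and 0.636 with an estimated correlation. The MHC median was -0.21 without Ras array 3. Erap1 (-1.58 ± 0.18), the alarmin Il33 (-2.84 ± 0.18) and Ccl20 (-1.30 ± 0.13) were lower. Counts were 302 genes higher and 186 lower, and the other 14 lists did not pass (adjusted p from 0.172 to 0.987). The luminal list lost its call (adjusted p = 0.0669 without dim genes, 0.0788 with the compared groups alone and 0.0716 without control array 3, all alternatives 7.9e-07 to 0.377). Ribosome biogenesis genes lost their call (adjusted p = 0.131 without dim genes, all alternatives 0.000814 to 0.673). The cytokine list lost its call (adjusted p = 0.0669 without dim genes, 0.052 with the compared groups alone, 0.0504 without control array 3 and 0.0604 without Ras array 3, all alternatives 0.00323 to 0.636). Cholesterol synthesis genes lost their call (adjusted p = 0.0544 without dim genes, all alternatives 1.96e-06 to 0.505). The immediate early list lost its call (adjusted p = 0.131 without dim genes, all alternatives 0.000336 to 0.43). When control array 3 was left out, the junction and Ras-ERK lists alone passed with an estimated correlation (adjusted p = 0.0115 and 0.0433).

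The Ras lines differed from the other oncogenes in the most genes, 537 higher and 451 lower. Nefm was at 10.17 ± 0.74 (SD, n = 3) against 4.48 ± 0.15 (n = 9) in the other lines (log2 fold change 5.69 ± 0.20, adjusted p = 5.78e-11), with Lipn (5.56 ± 0.20), the receptor Calcrl (4.94 ± 0.38), Cd34 (4.76 ± 0.22), C3ar1 (4.68 ± 0.16) and the basement membrane protein Nid1 (4.44 ± 0.12). Il1a, high in the other 3 groups, was at 4.69 ± 0.33 against 11.14 ± 0.26 (log2 fold change -6.45 ± 0.16, adjusted p = 1.77e-12). Krt7 (-6.20 ± 0.07), S100a14 (-5.81 ± 0.08), the serpin Serpinb5 (-5.31 ± 0.12), Epcam (-5.00 ± 0.06) and Bst1 (-4.90 ± 0.14) were lower. Of the Y-linked genes Eif2s3y was lower (-1.18 ± 0.19), while Uty and Kdm5d were at -0.26 and -0.35 (adjusted p = 0.115 and 0.187). As in NeuT, this came from the arrays labelled Myc (6.96, against 3.47 in Ras). Basal epithelial markers, luminal and secretory prostate markers and epithelial junction and identity genes fell in 17 of 19, 8 of 18 and 28 of 29 members, with the same counts adjusted over the list alone, and 1, 0 and 0 rose. Median changes of -1.75, -0.24 and -1.97 (log2) had adjusted p = 3.62e-12, 4.67e-05 and 9.03e-26, and adjusted p = 0.0956, 0.0198 and 0.0198 with an estimated correlation. Ribosome biogenesis genes and cholesterol synthesis genes fell in 18 of 26 and 14 of 17 members (19 and 14 adjusted over the list alone), and 0 of these rose. By camera, the lists had adjusted p = 1.02e-06 and 2.17e-06 at medians of -0.56 and -0.75 (log2), and adjusted p = 0.417 and 0.252 with an estimated correlation. P53 target genes and TGF-beta response genes fell in 12 of 17 and 11 of 19 members (13 and 12 adjusted over the list alone), and 0 and 4 rose. Median log2 changes were -0.51 and -0.54, at adjusted p = 4.67e-05 and 0.00927, and adjusted p = 0.255 and 0.202 with an estimated correlation. Krt14 (-4.39 ± 0.12), Esrp1 (-4.80 ± 0.12), Cyp51 (-1.38 ± 0.18) and Inhba (-3.68 ± 0.28) were among the lower members.

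Mesenchymal transition genes and matrix protease and inhibitor genes rose in 15 of 26 and 8 of 20 members (18 and 8 adjusted over the list alone), and 3 and 3 fell. Log2 medians were 0.67 and 0.13, at adjusted p = 5.38e-08 and 0.00378, and adjusted p = 0.0415 and 0.255 with an estimated correlation. The medians were 0.29 and 0.07 for the mesenchymal transition genes and matrix protease lists without Ras array 2. Cdh2 (3.31 ± 0.08), Vim (2.87 ± 0.08), the transcription factors Zeb1 (2.72 ± 0.10) and Prrx1 (4.36 ± 0.18), Mmp13 (3.19 ± 0.20) and Timp1 (1.96 ± 0.11) were higher. Fibroblast markers and interferon response genes rose in 5 of 15 and 6 of 22 members (7 and 4 adjusted over the list alone), and 0 of these fell (1 and 0 adjusted over the list alone). At log2 medians of 0.14 and 0.74, camera had adjusted p = 0.0388 and 0.000514, and adjusted p = 0.145 and 0.647 with an estimated correlation. Medians were 0.06 and 1.19 for the fibroblast markers and interferon response genes without Ras array 2, 1.14 for the interferon response genes without Ras array 1 and -0.02 for the interferon response genes without Ras array 3. The proteoglycan Dcn (2.86 ± 0.22) and the antiviral Ifit2 (2.18 ± 0.09) were higher. The fibroblast median was -0.15 with dim genes left out, so that its direction turned (adjusted p = 0.623, all alternatives 1.67e-05 to 0.624). Interferon response genes lost their call (adjusted p = 0.757 without Ras array 3, all alternatives 1.33e-06 to 0.757). In Ras array 3 alone Ifit1 was at 9.32 against 6.53 and 6.26 in Ras arrays 1 and 2. The cytokine list gained a call (adjusted p = 0.0173 without Ras array 2, all alternatives 0.0173 to 0.666). The glycolysis list gained a call (adjusted p = 0.00561 without Ras array 2, all alternatives 0.00561 to 0.666). They had adjusted p of 0.647 with an estimated correlation. With an estimated correlation and without control array 3, the basal, luminal, junction and mesenchymal lists alone passed (adjusted p = 0.00445, 0.0264, 0.00278 and 0.0264). In this contrast the other 14 lists did not pass (adjusted p from 0.137 to 0.99).

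In the Src lines, basal epithelial markers were higher than in the other oncogenes. Krt5 was at 12.19 ± 0.06 (SD, n = 3) against 6.84 ± 1.80 (n = 9) in the other lines (log2 fold change 5.35 ± 0.12, adjusted p = 3.7e-12), and the keratin Krt6a at 11.01 ± 0.02 against 6.83 ± 1.43 (log2 fold change 4.19 ± 0.17, adjusted p = 6.66e-10). Serpinb10 (4.76 ± 0.15), Il1f9 (4.50 ± 0.33), Tmem45a (4.45 ± 0.28) and the neuronal calcium sensor Vsnl1 (4.42 ± 0.18) were higher as well. Fam111a, which encodes a protease, was at 4.96 ± 0.44 against 10.48 ± 0.71 (log2 fold change -5.51 ± 0.16, adjusted p = 1.96e-11). The glutamine transporter Slc38a1 (-4.83 ± 0.14), the demethylase Alkbh3 (-2.68 ± 0.09) and Trps1 (-2.61 ± 0.20) were lower, with the Y-linked Eif2s3y (-0.98 ± 0.19), Uty (-0.46 ± 0.12) and Kdm5d (-0.59 ± 0.19). Again this came from the arrays labelled Myc, with Eif2s3y at 3.62 in Src. Basal epithelial markers, luminal and secretory prostate markers, epithelial junction and identity genes and TGF-beta response genes rose in 18 of 19, 5 of 18, 18 of 29 and 9 of 19 members (18, 8, 18 and 9 adjusted over the list alone), and 1, 0, 4 and 1 fell (1, 0, 5 and 1 adjusted over the list alone). Camera gave adjusted p = 5.63e-20, 4.57e-05, 2.95e-05 and 0.000994 at median changes of 1.79, 0.23, 0.50 and 0.18, and adjusted p = 0.0436, 0.0281, 0.576 and 0.137 with an estimated correlation. Trp63 (3.44 ± 0.10), Dsg3 (4.11 ± 0.15) and Tgfbi (3.18 ± 0.08) were among the higher members. Mitotic genes and cholesterol synthesis genes fell in 14 of 22 and 5 of 17 members (16 and 5 adjusted over the list alone), and 0 of these rose. With log2 medians of -0.46 and -0.28, the lists had adjusted p = 5.18e-08 and 0.00407, and adjusted p = 0.576 and 0.772 with an estimated correlation. Kif20a (-0.69 ± 0.11) and Insig1 (-1.11 ± 0.17) were lower. Against Myc, NeuT and Ras singly the medians were -0.15, -0.15 and 1.48 for the junction list, which thus rose through Ras alone, and -0.85, -0.41 and 0.42 for the cholesterol list. In this contrast 307 genes were higher and 220 lower, and the other 19 lists did not pass (adjusted p from 0.108 to 0.937). Cholesterol synthesis genes lost their call (adjusted p = 0.0561 without dim genes, all alternatives 0.00112 to 0.772). Ribosome biogenesis genes gained a call (adjusted p = 0.0329 without Ras array 1, all alternatives 0.0329 to 0.886). The MHC list gained a call (adjusted p = 0.0424 without Ras array 3, all alternatives 0.0424 to 0.886). These had adjusted p of 0.886 with an estimated correlation. When control array 3 was left out, the basal and luminal lists alone passed with an estimated correlation (adjusted p = 0.0013 and 0.0303).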

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

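The tests of the 3 patterns that follow were chosen only after the results were seen, while the regroupings of the arrays were planned.

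Control array 3 held transcripts of kidney tubules. The marker lists gave medians over the other controls of 3.38 for the proximal tubule (16 of 19 genes at least 2-fold higher), 3.22 for the thick ascending limb (6 of 8) and 1.18 for the distal tubule and collecting duct (7 of 13), and in control arrays 1 and 2 the median level of all values was exceeded by 2, 1 and 2 of these genes. Liver, intestine, skeletal muscle, seminal vesicle and urothelium lists lay between -0.12 and 0.03, podocytes at -0.11 and red blood cells at 0.35. Against another culture state of the same male cells stood Xist, higher by 4.85, and against an array wholly of another sample stood the basal epithelial markers, at a median of -0.56. Kidney RNA mixed into this sample, which may be from a female, stays as a candidate explanation, found and tested on the same array, and no biological explanation was tested since the design gives none.

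The Ras lines lost epithelial genes, with 28 of 29 junction and identity genes lower than in control. Near replacement of the cells by another type would raise that type's markers, but fibroblast markers had a median of 0.087 over control (range -1.40 to 1.14), leukocyte markers of -0.086 and smooth muscle markers of -0.28. The abundant fibroblast transcripts Col1a1 and Col1a2 were at 7.05 and 6.80 in the Ras arrays and 7.14 and 6.89 in control. These values argue against outgrowth of those 3 cell types. A change within the transformed epithelial cells may remain as a hypothesis, and a cell type without a list and the biological effect of Ras were not tested.

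Myc was lower in the arrays labelled Myc than in control, by a log2 difference of -0.92. An exchange with the NeuT label would need high Erbb2 in the arrays labelled Myc, where it was at -0.28 against the other lines. An unread transduced copy cannot be told apart from an absent one by the value of -0.92, since probe positions were not used here.

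The next results stand out because the effects against control went in opposite directions in a pair of oncogene groups, each passing its own test, with a test of the difference. Krt5 differed by 6.60 between Src and Ras (1.23 and -5.37, adjusted p = 8.39e-13), and Il1a by 6.68 between the same groups (5.49 and -1.19, adjusted p = 1.45e-11). Vim differed by 4.56 between Ras and the arrays labelled Myc (adjusted p = 3.61e-13). For Ras against NeuT, Ccl2 differed by 5.32 (adjusted p = 1.10e-11) and Egln3 by 4.20 (adjusted p = 8.69e-10), and for NeuT against Ras, Cpa4 by 5.66 (adjusted p = 1.86e-09) and Cldn6 by 3.24 (adjusted p = 4.46e-09). For Ras against Src, Dcn differed by 2.96 (adjusted p = 1.52e-06) and Timp1 by 2.81 (adjusted p = 2.39e-09). Src and the arrays labelled Myc differed in Tmem45a by 5.31 (adjusted p = 1.18e-07), Snai2 by 4.23 (adjusted p = 1.15e-10) and Trp63 by 3.53 (adjusted p = 2.80e-10), and NeuT and the arrays labelled Myc in Tnc by 5.75 (adjusted p = 1.60e-10). The lower side lay under 6.47 for Krt5, Il1a, Egln3, Cpa4, Dcn, Tmem45a, Snai2, Trp63 and Tnc, so that the sizes of these differences are unsure, and for Il1a, Egln3 and Tmem45a so did control, which leaves their falls unsure as well. The mesenchymal transition genes differed by a median of 1.11 between Ras and the arrays labelled Myc (adjusted p = 7.65e-11, and adjusted p = 0.0213 with an estimated correlation). The cholesterol synthesis genes differed by 0.99 between the arrays labelled Myc and Ras (adjusted p = 1.78e-08, and adjusted p = 0.161 with an estimated correlation). Among the 13767 probe sets with several genes or none, which no comparison used, 374 were higher and 153 lower in Ras than in control, against 176 and 628 for Myc, 170 and 540 for NeuT and 118 and 808 for Src. Against the other oncogenes the numbers were 958 and 77 for Ras, 35 and 115 for Myc, 71 and 142 for NeuT and 43 and 218 for Src.

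Other groupings of the same arrays were counted for each comparison. Pooled lines against control had 932 genes (1 of 100 splits as large, the real one included, highest other 9). The 4 oncogenes shared 269 (1 of 100, highest other 0). For both, the splits call too few genes to test chance. The F test had 2237 genes (1 of 100, highest other 1473). Against the other oncogenes, 448 genes were called for the arrays labelled Myc (2 of 100, highest other 900) and 488 for NeuT (3 of 100, 861). Ras had 988 (1 of 100, 412) and Src 527 (1 of 100, 224). The splits with 900 and 861 genes put the 3 Ras arrays together. Splits that mix arrays of different groups add the group differences to the spread, so that they call fewer genes by construction. These shares thus show that arrays of a group resemble each other. They cannot separate an oncogene from chance traits of the lines that carry it. For each oncogene against control the 10 splits are too few for a share under 0.05: 1288, 1182, 1412 and 886 genes for Myc, NeuT, Ras and Src stood against a highest other of 0, 0, 5 and 0, with 1 as large. The 6 pairs of oncogenes, with 10 splits each, had a highest other of 0.

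For the number of lists called, chance was not excluded: 11 lists for the pooled lines (28 of 100 splits as large, highest other 14), 9 for the arrays labelled Myc against the others (25 of 100, highest other 12), 11 for NeuT (10 of 100, 13), 11 for Ras (9 of 100, 12) and 6 for Src (59 of 100, 14). Against control the 10 splits per group are too few for a share under 0.05, with 13, 12, 13 and 10 lists for Myc, NeuT, Ras and Src beside a highest other of 12, 12, 14 and 10, and 1, 2, 4 and 2 splits as large.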

How the results depend on the processing

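All alternatives were planned except leaving out control array 3 with estimated list correlations. Across median centring, quantile normalization, averaged probe sets, a trended robust variance, array weights, fitting only the groups compared and the replicate block, the gene and list counts stayed within 1.5 times. Leaving out each of the 15 arrays kept every total within 1.5 times. Genes that rose in all 4 groups went from 82 to 53 without control array 3. The pooled lines against control gave 839 to 1175 genes and Ras against control 1372 to 1500. Src against the others gave 514 to 534, genes shared by 4 oncogenes 234 to 339 and the F test 2194 to 2316. With dim genes left out, which means fewer genes tested, the genes shared by 4 oncogenes numbered 169 and the lists called for NeuT against the others 6, and the cause for the lists was not tested. The fibroblast markers turned from 0.14 to -0.15 for Ras against the others. Among single-list results with dim genes left out, 15 calls were lost, that one included, and 2 gained.

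With no fold minimum, which admits more genes by construction, 5730, 5699, 5339, 5469 and 5263 genes were called for the pooled lines, Myc, NeuT, Ras and Src against control. The contrasts with the other oncogenes gave 4096, 4184, 6277 and 4048. The pairs gave 2979 (Myc and NeuT), 5665 (Myc and Ras), 3777 (Myc and Src), 5607 (NeuT and Ras), 4019 (NeuT and Src) and 5214 (Ras and Src), the shared genes numbered 1474 and the F test gave 8386. With estimated correlations, 1, 0, 0, 3 and 0 lists were called for the pooled lines, Myc, NeuT, Ras and Src against control and 0, 0, 3 and 2 for the 4 oncogenes against the others. With control array 3 also left out, these counts were 8 for the pooled lines, 5, 5, 6 and 2 for the 4 oncogenes against control and 3, 2, 4 and 2 against the others. Fry called 14 lists for Myc against the others, and gained 30 and lost 7 list calls in all. The causes were not tested.

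The replicate block takes the numbers in the labels as a shared factor. It gained 1 list call (interferon response genes in NeuT against control, adjusted p = 0.0478). It changed the side of the threshold for 3 named-gene results in each direction. The numbers did not pair the samples clearly: 30 same-number pairs across groups had a median residual correlation of 0.023 and 60 others -0.013, while 10 of the 15 arrays correlated best with their own number. Background was not measured here, so that levels under 6.47, a median, may lie near it.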

Other observations

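The sets given here were chosen only after their values were seen. Genes whose group mean lay at least 8-fold above or below each of the other 3 oncogene groups numbered 33 higher and 30 lower in Ras, 14 and 3 in Src, 4 and 0 in NeuT and 2 and 1 in the arrays labelled Myc. In Ras, the cell adhesion molecule Vcam1 was at 9.86 against 5.81 to 6.14 in the other lines, the collagen receptor Ddr2 at 9.35 against 5.97 to 6.10 and the DNA sensor Aim2 at 9.73 against 5.20 to 5.43.

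Of the 14 genes higher in Src, the iron-binding Ltf was at 8.77 against 5.18 to 5.30, the cornified envelope gene Sprr2d at 9.62 against 5.64 to 6.37, and the glutathione peroxidase Gpx2 at 9.55 against 5.81 to 6.10.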
